A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

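RNA from 2 yeast strains, the parental strain BGL-6Kl and the strain labelled YGP1 deletion, was sequenced in 2 biological replicates each, per the labels. Per the labels' protocols, total RNA was extracted with TRIzol from cultures grown for 48 h and libraries were made by standard Illumina procedures. The aligner, read counter, genome build, annotation, strandedness and statistical test are not given in the sources used here. Without known strandedness, reads of overlapping and antisense genes cannot be told apart, and how reads of near-identical copies were assigned is likewise not known. Where nothing says otherwise, p-values measure the spread between these 2 libraries per strain only.

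One deposited table was used. Per the file headers it holds a read count per strain, and the values show this signal to be the mean of both libraries' read counts after the authors divided each library by a size factor. The deposited log2 fold change is that of the deletion strain over the parent, and it equals the log2 ratio of the 2 means to within 5e-05. The authors also deposited a p-value and an adjusted p-value per feature and a call that is true exactly where the adjusted p-value is below 0.05. The adjusted p-value of the feature with the smallest p-value implies between 6576 and 6646 tests, more than the 6484 features listed, so some tested features are not analysed here. Of the listed features, 76 had a mean of 0 in the parent, and no feature had a mean of 0 in the deletion strain. Feature names were matched to locus tags of the R64 assembly for 5869 of 6484 features. The other 615 were used as named by the authors. Since the authors' build is not given, R64 served for names, neighbours, overlaps and coding lengths only, and no coordinates are printed.

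Each strain mean is a whole number of reads of one library times one step plus a whole number of reads of the other times another step. Both steps were fitted by least squares, and all pairs of whole reads that gave the deposited value to within 0.55 units of its last digit were listed. The solution was unique for 6325 features in the parent (97.5%) and 6179 in the deletion strain (95.3%), and no feature lacked a solution. Features without a unique solution were mostly abundant: above a mean of 20000, 37.9% were solved in the parent and 0 of 161 in the deletion strain. Values between 0 and 1000 that were shifted off the grid had a solution in 0.08% of cases in the parent and 0.11% in the deletion strain. Larger values were not tested in this way. The steps give size factors of 1.155 and 0.9636 for parental libraries A and B and of 1.125 and 0.7968 for deletion libraries A and B, within 0.81% of median-of-ratios factors recomputed from the recovered reads. In data simulated from the authors' strain means, each of the 6350 and 6173 unique solutions equalled the simulated reads. Since all fitting pairs are listed, this had to follow once the steps were fitted correctly, so it tests the fit of the steps only.

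The design written before the data were examined called for a test per library by the unit of the values, and for a description of the authors' values where only strain means were given. The authors' adjusted p-values and calls are therefore the main result. Their size factors assume that most features do not change, and a mean gives no spread of its own. As an added alternative, limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, 2-sided, Benjamini-Hochberg adjustment) was fitted to log2(normalised read count + 1) of the 4 recovered libraries for 6068 features with a mean of at least 1. Fold changes of that fit are on the log2(value + 1) scale, which understates the change of low features. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so none was used for single features. Tested on simulated data with 6083 features fitted, the limma fit called 82.3% of features changed 2-fold and 100% of those changed 4-fold, and 9 of its 179 calls were unchanged features. All simulated features shared 1 dispersion and varied independently, only 200 were changed, and no culture difference was simulated. These rates therefore need not hold for the real libraries.

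Gene lists were fixed before the data were examined, 42 in all. The design named limma's camera on the log2 values of the main fit. With strain means only, the pre-ranked form of camera was used instead, on the authors' p-values turned into signed z-scores, with the preset correlation of 0.01, features with a mean of at least 1, lists of at least 5 members, YGP1 left out and Benjamini-Hochberg adjustment over 41 lists. Camera with the preset and with an estimated correlation, and fry, were run on the recovered libraries. Camera with an estimated correlation was also run there for the added gene sets with at least 5 recovered members. In simulated data a list of raised features was found and 0 of 200 unchanged lists passed. The simulated features varied independently, so this does not test lists whose members vary together. The estimated correlation of the cytosolic ribosomal protein genes, for example, was 0.74.

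Genes were named by a rule set before the data were examined: YGP1, its paralog and 5 neighbours, then, among calls with a larger strain mean of at least 5 whose libraries do not overlap between strains, the 12 largest rises and 12 largest falls, and up to 4 members with the smallest p for each list described. Calls without recovered reads were kept in this rule. SED1 in the report was chosen after its value was seen. Not all genes that this rule names are reported here. A feature with 0 reads in the parent was ranked by its lower bound against 3 reads over the parental libraries (a normalised value of 1.56). Features with 1 to 3 reads in a strain are given with the ratio of reads, scaled by the libraries' size factors, and its exact 95% interval. Both cover counting error only. Alternatives were the pseudocount (0.1 and 5), no low value filter and a mean of at least 10, rescaling by median ratios, quantile normalisation, limma without an intensity trend, each library left out, and a 2-fold threshold. Further computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.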

Results

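RNA was sequenced from 2 strains of the budding yeast Saccharomyces cerevisiae, the parental strain BGL-6Kl and a derivative of it labelled as a YGP1 deletion, with 2 libraries per strain that the labels call biological replicates. Both strains were grown in YPD, a rich glucose medium, for 48 h at 30 °C and 200 rpm. The series gives this as the earliest time at which the activity it calls BGL, measured on whole cells, clearly differed between the strains. The comparison asks which transcripts differed at that time. The authors' deposited table holds 6484 features with a mean normalised read count per strain, a fold change and an adjusted p. Reads of each library were recovered from these means for 6136 features in both strains. Over the 6325 features solved in the parent, the recovered reads summed to 14376030 and 12043457 in parental libraries A and B. Over the 6179 solved in the deletion strain, they summed to 10005304 and 7302856 in its libraries A and B. Most of the most abundant features had no unique solution and are not in these sums. Above a mean of 20000, the parental sums hold 74 of 195 features and the deletion sums 0 of 161, so the sums do not compare depth between strains. Library letters order the libraries of a strain by depth and are not the replicate numbers of the labels. Values below are the authors' strain means, which carry no SD, followed where possible by the recovered values of both libraries. Over 5219 features with at least 50 reads in each library, the median absolute log2 difference was 0.18 between the parental libraries, 0.28 between the deletion libraries and 0.47 between the strains. Across these features the log2 values of parental library A correlated at 0.909 with each deletion library. Those of parental library B correlated at 0.873 and 0.877 with deletion libraries A and B. Parental library A thus lay closer to the deletion strain, so differences between cultures can enter any comparison below.

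YGP1 (YNL160W), which encodes a secreted glycoprotein, was lower in the strain labelled as its deletion but remained well above 0. Its mean normalised read count was 62470 in the parent and 18171 in the deletion strain, 29.1% of the parental level (log2 fold change -1.78, adjusted p = 2.88e-08 in the authors' deposited table). By its mean it still ranked 185 among the features of the deletion strain, against 47 in the parent. For each strain 3 pairs of whole reads fit the YGP1 mean, so the values of libraries A and B are not known. In the parent they were 14687 and 110252, 57637 and 67302, or 91601 and 33338. In the deletion strain they were 3699 and 32644, 18027 and 18316, or 32355 and 3987. Only the second pair of each strain lies less than 2-fold apart. Among features with at least 50 reads in each library, 1.0% in the parent and 3.1% in the deletion strain were at least 2-fold apart. The total of a gene does not show which part of it the reads cover, so this check of the labels is incomplete. The second strain is called the strain labelled YGP1 deletion, or deletion strain for short. The paralog SPS100 (YHR139C) had means of 95893 and 173582 (log2 fold change 0.86), overlaps a noncoding gene on the opposite strand in R64, and did not pass the test (adjusted p = 0.878 in the authors' deposited table). Of the 5 fixed neighbours of YGP1, 1 changed: RPL42A, a ribosomal protein gene, was 2.95-fold lower (1235 and 1641 in the parental libraries, 550 and 424 in the deletion libraries, adjusted p = 0.000122 in the authors' deposited table). Cytosolic ribosomal protein genes as a list, RPL42A among them, had a median log2 fold change of -1.17, so its fall is not particular to this locus. CBK1, ASI2, PGA1 and IGO1 had log2 fold changes between -0.40 and 0.03 in the authors' deposited table and did not pass.

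The authors' deposited table called 1296 features changed at an adjusted p below 0.05, 20% of those listed. Of these, 626 were higher and 670 lower in the deletion strain, and 887 differed at least 2-fold (435 higher, 452 lower). The list holds 76 features with a mean of 0 in the parent but 0 such features in the deletion strain, and not all tested features are listed. Falls to a mean of 0 may therefore be missing from these counts and from the falls named below. Among the called features, 1192 had recovered reads, and in each of these both deletion libraries lay on the same side of both parental libraries, which a call from 2 libraries against 2 largely requires. Of all 6136 recovered features 66.1% were separated in this way, where chance gives 33.3% for 2 libraries against 2. A limma fit to the recovered libraries, chosen after the data were seen, called 1742 of 6068 features (843 higher, 899 lower). Of the authors' calls, 1191 of the 1192 it could test were among them, all in the same direction. This is no separate check, because the fit used the same 4 libraries, and the separation of the libraries fixes the direction. Without the intensity trend limma called 691 (371 higher, 320 lower), so the larger direction turned, as it also did without parental library B. The count of 1742 also rested on single libraries: it was 1354 without parental library A, 822 without parental library B, 440 without deletion library A and 429 without deletion library B.

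**Figure D1:**
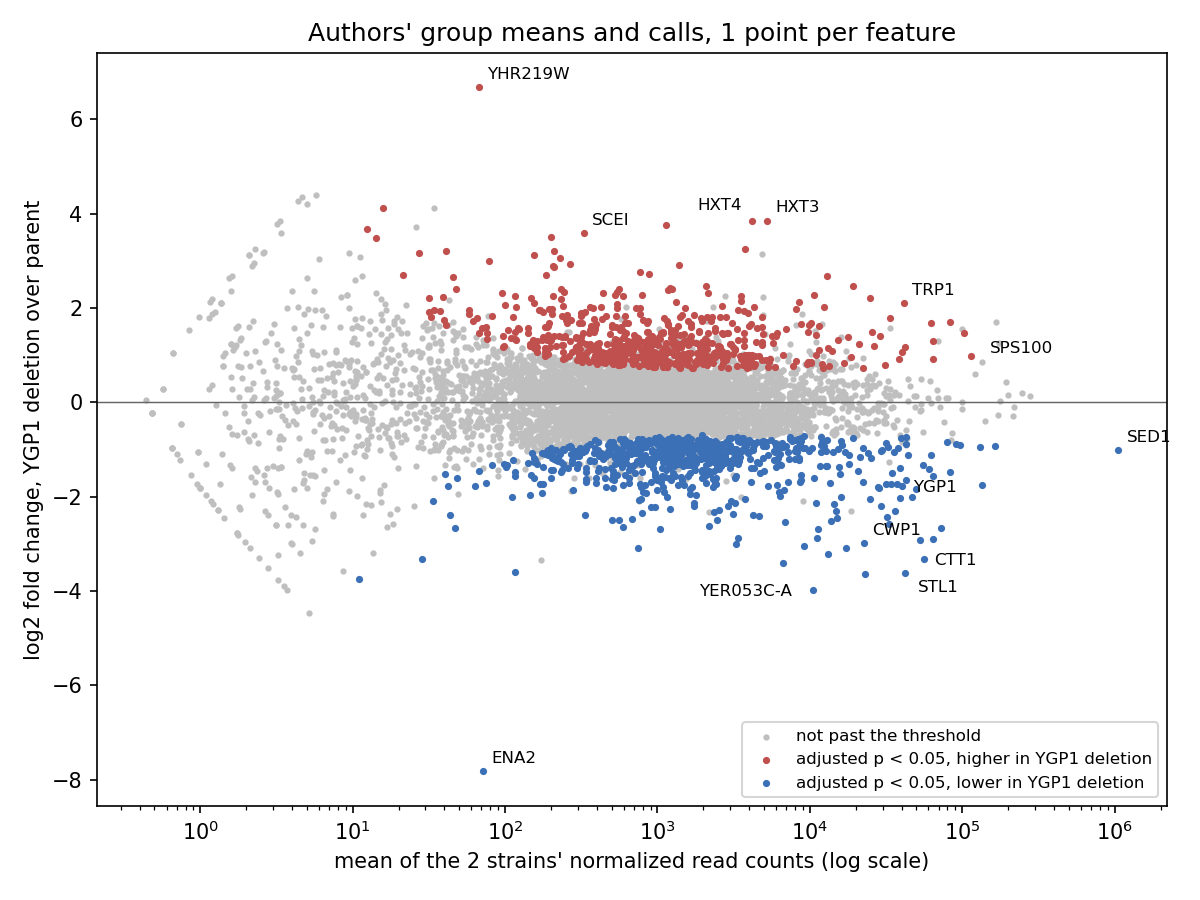
Log2 fold change of the deletion strain over the parent (vertical axis) against the mean of both strains' normalised read counts (horizontal axis, log scale), 1 point per feature with a parental mean above 0, from the authors' group means. Coloured points are the calls at an adjusted p below 0.05 (626 higher in red, 670 lower in blue), except that 2 of the higher ones, with a parental mean of 0, are not drawn, and YGP1 lies at -1.78.

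The 12 largest rises included a pair of hexose transporter genes. HXT4 and HXT3 were 14.4-fold higher each: HXT4 had 626 and 456 in the parental libraries and 8500 and 7081 in the deletion libraries, and HXT3 had 862 and 499 against 10932 and 8631 (adjusted p = 1.58e-31 and 8.43e-23 in the authors' deposited table). IMA5, an isomaltase gene, was 11.3-fold higher (adjusted p = 0.000121 in the authors' deposited table). The uncharacterised genes YJL213W and YGR035C were 13.6-fold and 9.48-fold higher (adjusted p = 1.95e-10 and 4.44e-23 in the authors' deposited table). SCEI (Q0160), a mitochondrial endonuclease gene inside an intron, rose by a log2 fold change of 3.59 in the authors' deposited table, with 66.7 and 34.2 in the parental libraries and 528 and 686 in the deletion libraries. It overlaps the large mitochondrial ribosomal RNA gene (Q0158) on the same strand in the R64 annotation, so its reads may belong to either. The other rises had few parental reads. YHR219W, a subtelomeric open reading frame, had 3 reads in the parent and 250 in the deletion strain. Scaled by the size factors this is a ratio of 91.9 (95% exact counting interval 31.1 to 448), against 102-fold in the authors' deposited table. RDN5-2, one of several near-identical 5S ribosomal RNA copies, had 0 reads in the parent and 84 in the deletion strain. It was at least 30.0-fold higher against a floor of 3 reads over the parental libraries. YJR029W, a retrotransposon reading frame with near-identical copies elsewhere, was 17.4-fold higher, Novel00011, an unnamed feature of the authors, 12.7-fold, YER068C-A 11.1-fold and YCR102W-A 9.28-fold, all from parental means below 8 (adjusted p = 0.00511, 0.0245, 0.022 and 9.99e-05 in the authors' deposited table).

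The largest fall among the listed features was that of ENA2, a sodium pump gene with near-identical neighbours ENA1 and ENA5. ENA2 had 309 reads in the parent and 1 in the deletion strain. Scaled by the size factors this is a ratio of 280 (95% exact counting interval 49.9 to 11107), against 227-fold in the authors' deposited table. STL1, the glycerol transporter gene, fell from 78096 to 6357, a 12.3-fold difference (adjusted p = 1.49e-28 in the authors' deposited table). CTT1, the cytosolic catalase, fell from 101249 to 10108 (log2 fold change -3.32, adjusted p = 2.3e-06), and FMP48 12.5-fold lower (42400 and 3403, adjusted p = 2.07e-07 in the authors' deposited table). SCW11 and DSE1, both expressed in daughter cells, were 10.7-fold and 8.46-fold lower (adjusted p = 0.0112 and 0.0342 in the authors' deposited table). The SCW11 values were 7845 and 16344 in the parental libraries and 1118 and 1147 in the deletion libraries. ARO4, an enzyme of aromatic amino acid synthesis, was 8.58-fold lower, with 856 and 1809 against 154 and 157 (adjusted p = 0.0216 in the authors' deposited table). YER053C-A was 15.7-fold, YLR285C-A 12.2-fold, PNS1 9.34-fold and HMRA2, from a silent mating cassette whose sequence recurs at other mating loci, 9.95-fold lower (adjusted p = 1.45e-06, 0.00243, 1.08e-07 and 0.00115 in the authors' deposited table). YBR116C had 43 reads in the parent and 3 in the deletion strain. Scaled by the size factors this is a ratio of 13.0 (95% exact counting interval 4.16 to 65.5), against 13.4-fold in the authors' deposited table. The intervals cover counting error only. The limma results that follow rest on the same 4 libraries as the authors' calls, so they are no separate check. With limma on the recovered reads 20 of these 24 rises and falls passed, and the other 4 could not be tested because their reads were not recovered; without deletion library A 11 passed and without deletion library B 13.

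**Figure D2:**
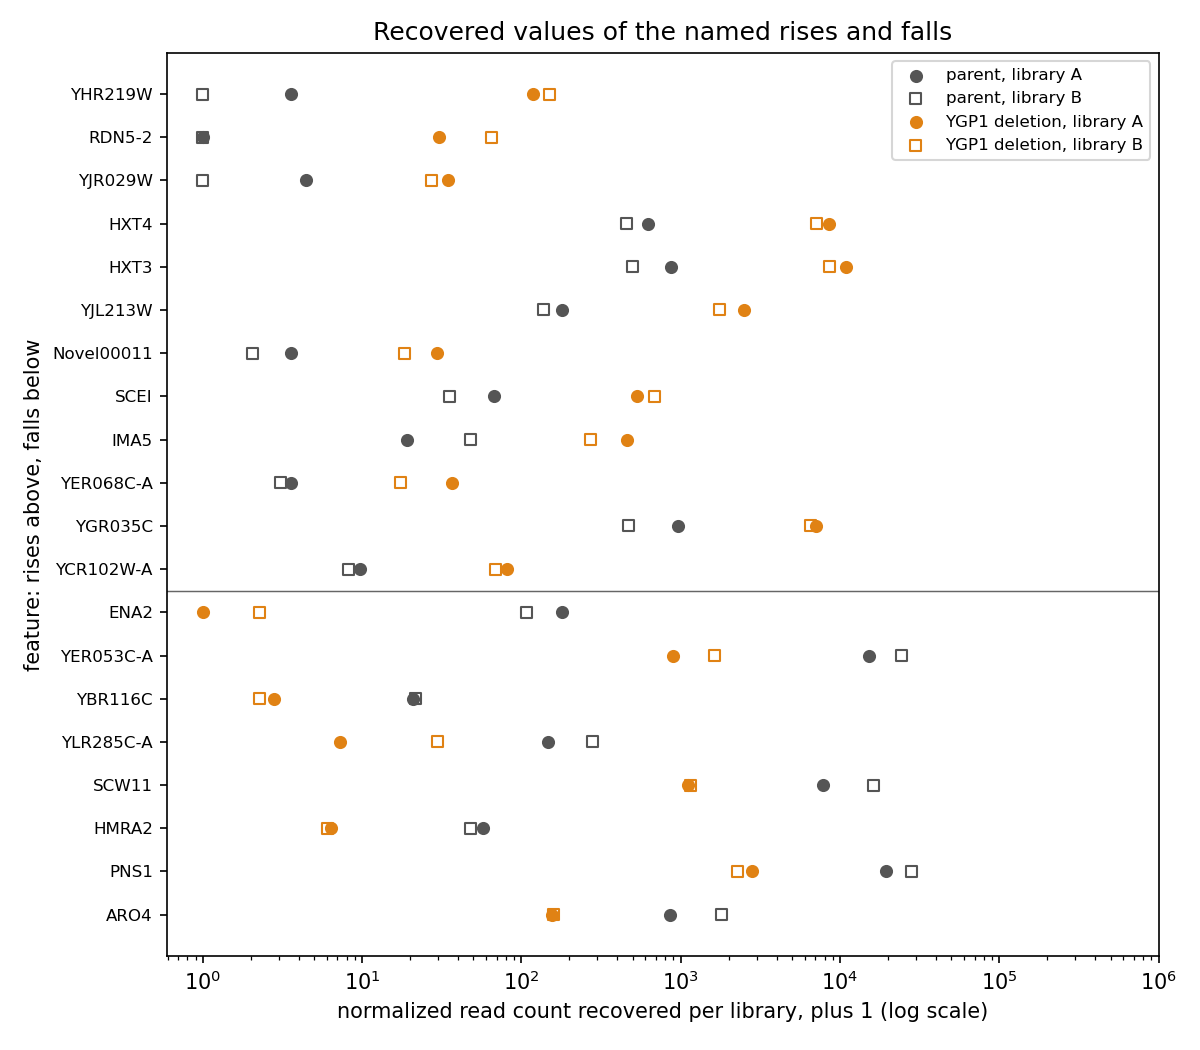
Recovered normalised read count plus 1 in each library (horizontal axis, log scale) for the 20 named rises (above the line) and falls (below it) whose reads were recovered in both strains, with filled circles for library A and open squares for library B of each strain. The rule for naming features took only those whose libraries do not overlap between strains, so the separation shown follows from the choice; HXT3, for example, had 862 and 499 in the parent and 10932 and 8631 in the deletion strain.

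Of the 41 gene lists that could be tested, fixed before the data were examined, 20 stood apart from the other features in a pre-ranked camera test on the authors' p-values, 9 upward and 11 downward. None of the 41 lists passed when limma's camera estimated the correlation between members from the 4 recovered libraries (adjusted p from 0.59 to 0.95, 0 lists at an unadjusted p below 0.05), while fry, which asks whether a list moves on balance in one direction, passed 2, the hexose transporters and oxidative phosphorylation. The adjusted p with an estimated correlation is given beside each of the 20 lists. With 2 libraries per strain that test keeps few residual degrees of freedom, so hardly any list could pass it. The hexose transporters and oxidative phosphorylation had estimated correlations of -0.048 and -0.021, below the preset 0.01. Their camera adjusted p on the recovered libraries still went from 0.00833 and 0.0116 to 0.59. That value alone therefore does not measure how far correlated members made a list pass. Among the 20 lists the highest estimates were 0.74 for cytosolic and 0.55 for mitochondrial ribosomal proteins and 0.60 for daughter cell separation. Ribosome biogenesis had 0.45 and phospholipid synthesis 0.44. Where members vary together this much, the preset of 0.01 makes the camera p-value too small. With the preset correlation on the recovered libraries 13 of the 20 passed. The 7 that did not were heat shock chaperones, ethanol and acetate metabolism, the TCA cycle, fatty acid oxidation, the general stress response, stationary phase genes and phosphate regulation. Reads were recovered for 7 of 28 chaperone genes, 7 of 16 ethanol and acetate genes and 16 of 18 fatty acid oxidation genes.

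**Figure D3:**
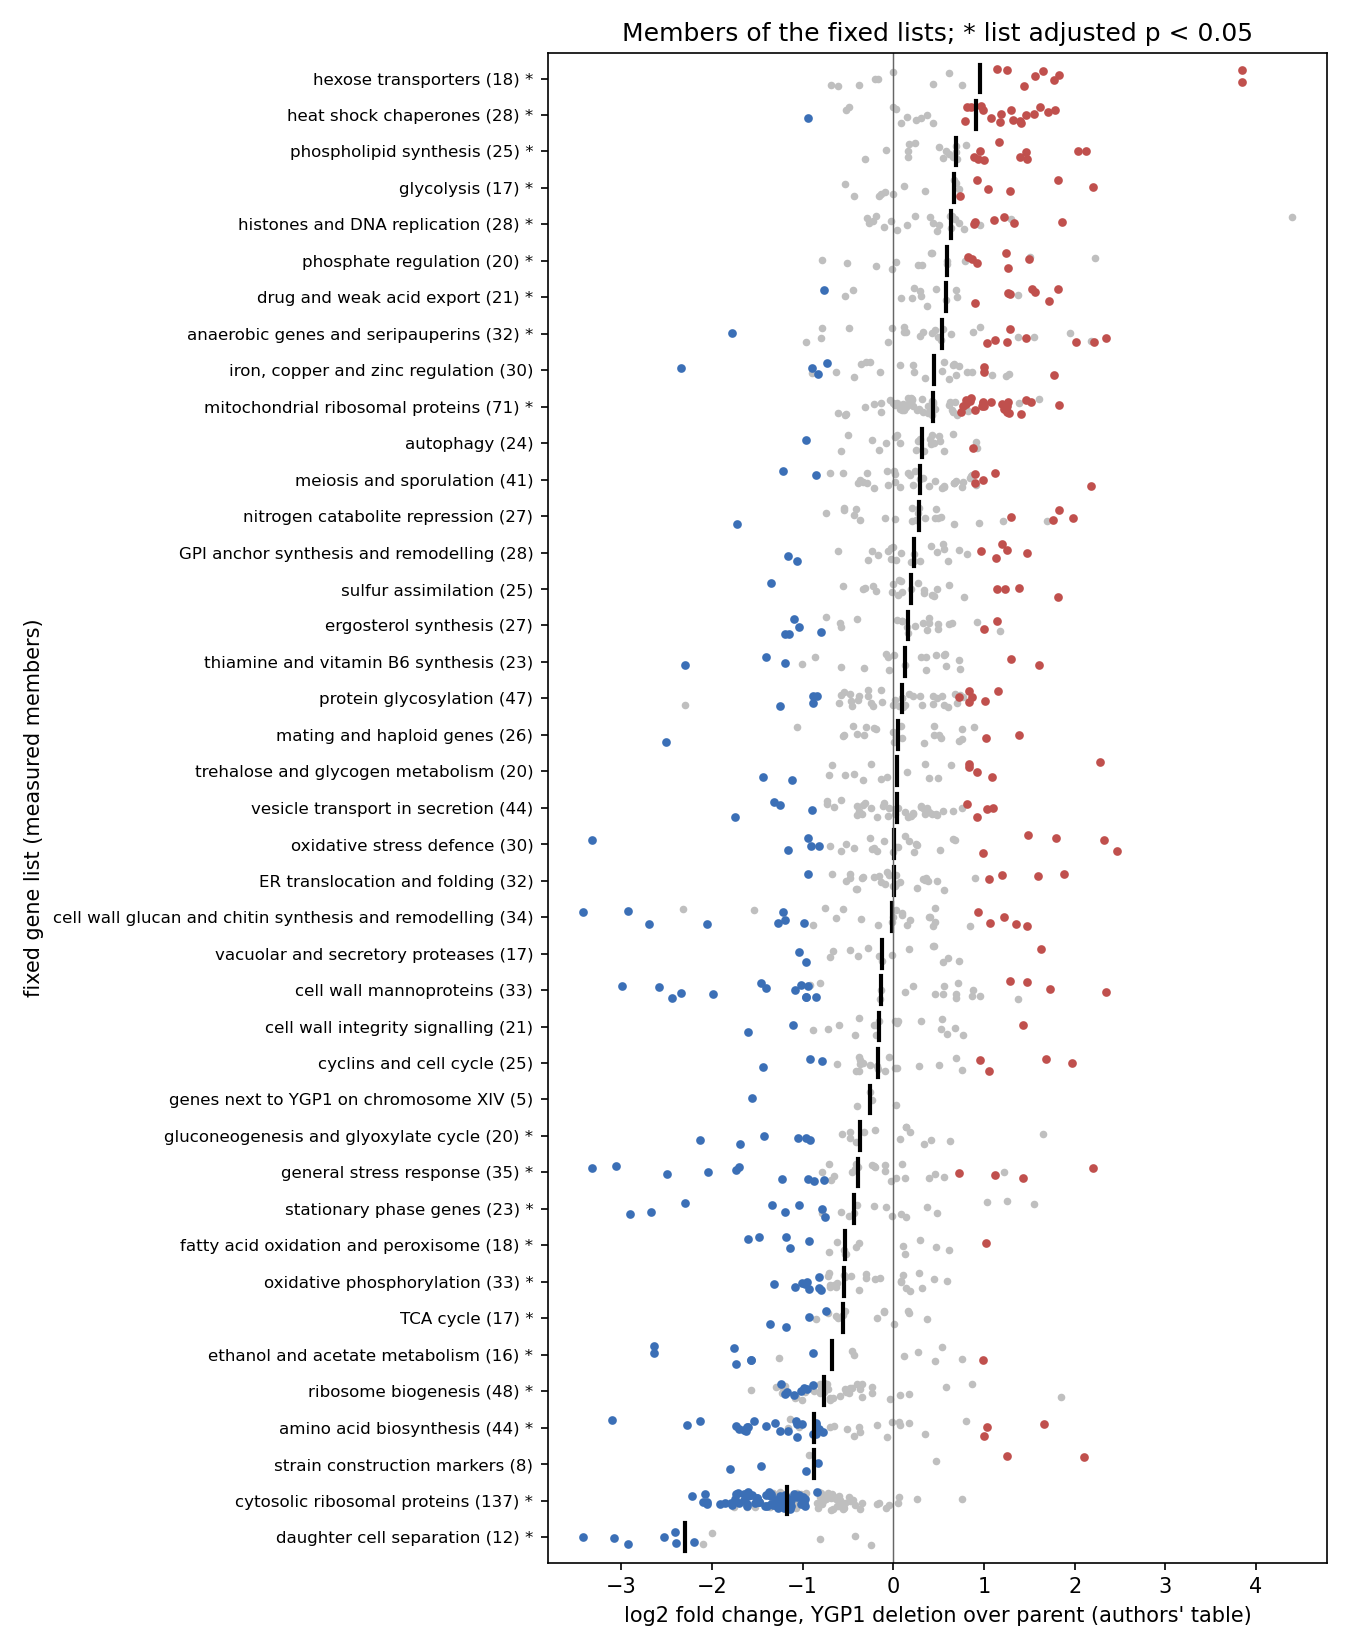
Log2 fold change of the deletion strain over the parent in the authors' deposited table (horizontal axis) for each measured member of the 41 tested lists, with a black bar at the list's median and the number of members in brackets. Red and blue points passed an adjusted p of 0.05, grey points did not, and a star marks the 20 lists that passed; daughter cell separation lies lowest with a median of -2.29 and hexose transporters highest with 0.95.

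In the lists of sugar uptake and glycolysis the genes that passed rose, and in those of respiration and gluconeogenesis they fell, while 50% or more of the members of each did not pass. Among 18 hexose transporter genes 9 rose and 0 fell (9 and 0 adjusted over the list alone, median log2 fold change 0.95, camera adjusted p = 1.37e-05). With an estimated correlation that list had adjusted p = 0.59. Besides HXT3 and HXT4, HXT11 was 3.54-fold and HXT7 2.71-fold higher (adjusted p = 5.83e-06 and 9.09e-06 in the authors' deposited table), but HXT11 and HXT9, like HXT7 and HXT6, are near-identical pairs between which reads could be split. Of 17 glycolysis genes 6 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0147, and adjusted p = 0.59 with an estimated correlation). ENO2, an enolase, was 3.52-fold, the hexokinase HXK1 4.60-fold, GPM1 2.44-fold and HXK2 2.06-fold higher (adjusted p = 1.11e-06, 0.000121, 0.000312 and 0.00492 in the authors' deposited table). Ethanol and acetate metabolism had 7 falls and 1 rise among 16 genes (8 and 2 adjusted over the list alone, camera adjusted p = 0.00189, and adjusted p = 0.62 with an estimated correlation). PDC6, a pyruvate decarboxylase, was 6.20-fold lower (3870 and 3664 in the parent, 676 and 540 in the deletion strain, adjusted p = 3.04e-15 in the authors' deposited table). The aldehyde dehydrogenases ALD4 and ALD3 were 3.36-fold and 3.33-fold lower (adjusted p = 9.96e-06 and 1.26e-05 in the authors' deposited table). Of 20 genes of gluconeogenesis and the glyoxylate cycle 6 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.00595, and adjusted p = 0.59 with an estimated correlation). ICL1, isocitrate lyase, was 4.38-fold lower, and the ammonium and acetate transporter genes ATO3 and ATO2 were 3.24-fold and 2.68-fold lower (adjusted p = 1.97e-11, 1.33e-07 and 0.00127 in the authors' deposited table). The TCA cycle had 4 falls and 0 rises among 17 genes (6 and 0 adjusted over the list alone, camera adjusted p = 0.00949, and adjusted p = 0.60 with an estimated correlation). LSC2 was 2.56-fold and SDH3 2.26-fold lower in the authors' deposited table. Oxidative phosphorylation had 9 falls and 0 rises among 33 genes (15 and 0 adjusted over the list alone, camera adjusted p = 0.000654, and adjusted p = 0.59 with an estimated correlation). QCR2, of complex III, was 2.50-fold lower (adjusted p = 9.93e-05 in the authors' deposited table). Fatty acid oxidation and peroxisome genes had 5 falls and 1 rise among 18 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0468, and adjusted p = 0.62 with an estimated correlation). PXA1, a peroxisomal transporter, was 3.02-fold lower and PEX13 2.03-fold higher (adjusted p = 1.63e-06 and 0.00481 in the authors' deposited table).

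Among genes that act when daughter cells separate from their mothers all that passed fell, while cell wall genes changed in both directions. In the daughter cell separation list 7 of 12 genes fell and 0 rose (7 and 0 adjusted over the list alone, median log2 fold change -2.29, camera adjusted p = 0.000781, and adjusted p = 0.59 with an estimated correlation). ASH1, a daughter cell repressor, was 5.29-fold lower (6023 and 9675 in the parent, 1084 and 1884 in the deletion strain), DSE3 5.24-fold and the chitinase CTS1 7.57-fold lower (adjusted p = 0.00133, 0.0079 and 0.0259 in the authors' deposited table). Of 33 cell wall mannoprotein genes 13 fell and 4 rose (14 and 7 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0701). Its test pointed down on the authors' p-values and up on the recovered libraries, which held 21 of its 33 members. Among the members missing there were CCW12, CCW14, CWP1, CWP2, HSP150, PIR1, PIR3 and SED1, all called lower. The upward direction leaves out these falls and does not describe the whole list. CWP1 was 7.92-fold and PIR1, a covalently linked wall protein, 6.01-fold lower, FIT1 5.06-fold lower and the flocculin FLO5 3.31-fold higher (adjusted p = 4.62e-21, 1.94e-14, 1.95e-10 and 3.17e-07 in the authors' deposited table). FLO5 has close copies, so its reads are uncertain. SED1, another wall protein and the most abundant transcript, was 2.02-fold lower (1412040 and 698121, adjusted p = 0.0112 in the authors' deposited table). Genes of glucan and chitin synthesis had 5 rises and 8 falls among 34 (6 and 12 adjusted over the list alone, camera adjusted p = 0.365). The glucan synthase FKS1 was 2.55-fold higher, and KRE9, NCA3 and CRH1 were 2.41-fold, 4.14-fold and 2.30-fold lower in the authors' deposited table. Cell wall integrity signalling had 1 rise and 2 falls among 21 (1 and 2 adjusted over the list alone, camera adjusted p = 0.688): MKK1 was 2.69-fold higher, and WSC3 and SLT2 were 3.04-fold and 2.15-fold lower in the authors' deposited table.

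The fixed lists of the secretory pathway did not pass. ER translocation and folding had 4 rises and 1 fall among 32 genes (4 and 1 adjusted over the list alone, camera adjusted p = 0.532). The thiol oxidase ERO1 was 3.69-fold and the chaperone KAR2 2.08-fold higher (adjusted p = 4.92e-09 and 0.00207 in the authors' deposited table). Vesicle transport had 4 rises and 4 falls among 44 (camera adjusted p = 0.965), protein glycosylation 6 rises and 4 falls among 47 (camera adjusted p = 0.669), and both had the same counts adjusted over the list alone. SEC8, of the exocyst, was 3.36-fold and SSO2, a plasma membrane SNARE, 2.49-fold lower in the authors' deposited table. GPI anchor synthesis had 5 rises and 2 falls among 28 (7 and 2 adjusted over the list alone, camera adjusted p = 0.134), and CWH43 was 2.38-fold higher in the authors' deposited table. Vacuolar and secretory proteases had 1 rise and 2 falls among 17 (1 and 2 adjusted over the list alone, camera adjusted p = 0.896). YPS6, a yapsin, was 3.08-fold higher and YPS1 1.94-fold lower (adjusted p = 3.66e-07 and 0.00551 in the authors' deposited table).

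Of the heat shock chaperone genes that passed all but 1 rose, whereas the general stress list had more falls than rises and the stationary phase list falls only. In the latter lists 21 of 35 and 15 of 23 genes did not pass. Of 28 chaperone genes 17 rose and 1 fell (17 and 1 adjusted over the list alone, median log2 fold change 0.91, camera adjusted p = 2.99e-07, and adjusted p = 0.59 with an estimated correlation from 7 recovered members). The cytosolic Hsp70 genes SSA1 and SSA2, which are close copies of each other, were 3.26-fold and 3.06-fold higher, the cyclophilin CPR6 2.93-fold (4341 and 2803 in the parent, 11069 and 9843 in the deletion strain) and MDJ1 2.64-fold higher (adjusted p = 1.92e-07, 8.49e-07, 2.21e-06 and 1.3e-05 in the authors' deposited table). General stress response genes had 10 falls and 4 rises among 35 (12 and 4 adjusted over the list alone, camera adjusted p = 0.00569, and adjusted p = 0.59 with an estimated correlation). Besides CTT1, GRE2 was 8.33-fold lower (16904 and 15697 against 1863 and 2052), and GPD1, of glycerol synthesis, and NQM1 were 4.10-fold and 3.25-fold lower (adjusted p = 7.41e-22, 5.4e-10 and 1.08e-07 in the authors' deposited table). Stationary phase genes had 8 falls and 0 rises among 23 (8 and 0 adjusted over the list alone, camera adjusted p = 0.00189, and adjusted p = 0.59 with an estimated correlation). SNZ1, of vitamin B6 synthesis, was 4.92-fold, FMP45 7.47-fold and PHM7 6.36-fold lower (adjusted p = 6.7e-14, 2.43e-05 and 0.000102 in the authors' deposited table). Oxidative stress defence had 5 rises and 5 falls among 30 (7 and 6 adjusted over the list alone, camera adjusted p = 0.559). The peroxiredoxin AHP1 was 5.53-fold and the oxidoreductase OYE3 4.99-fold higher (adjusted p = 1.24e-11 and 1.77e-12 in the authors' deposited table).

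Cytosolic ribosomal protein genes had the smallest camera p of all lists. All of them that passed fell, and all of their mitochondrial counterparts that passed rose, while 70 of 137 and 48 of 71 did not pass. Of 137 cytosolic ribosomal protein genes 67 fell and 0 rose (93 and 0 adjusted over the list alone, median log2 fold change -1.17, camera adjusted p = 3.16e-19, and adjusted p = 0.59 with an estimated correlation). RPS3 was 4.28-fold lower (4573 and 5233 in the parent, 1420 and 872 in the deletion strain), RPL11A 3.36-fold, RPL19B 2.88-fold and RPL10 2.79-fold lower (adjusted p = 5.09e-10, 1.9e-06, 1.41e-05 and 1.5e-05 in the authors' deposited table). Many of these genes are duplicated, so reads could be split between the copies. Parental library B lay above parental library A in this list by a median log2 difference of 0.57. For deletion library B over deletion library A the median log2 difference was -0.17. Of 48 ribosome biogenesis genes 8 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.000115, and adjusted p = 0.60 with an estimated correlation). RRN3, of RNA polymerase I transcription, was 1.94-fold lower in the authors' deposited table. Of 71 mitochondrial ribosomal protein genes 23 rose and 0 fell (26 and 0 adjusted over the list alone, median log2 fold change 0.44, camera adjusted p = 2.02e-06, and adjusted p = 0.62 with an estimated correlation). MRPS8 was 3.55-fold and IMG1 2.87-fold higher (adjusted p = 4.99e-07 and 5.94e-06 in the authors' deposited table). Amino acid biosynthesis genes had 24 falls and 3 rises among 44 (26 and 3 adjusted over the list alone, median log2 fold change -0.87, camera adjusted p = 2.99e-07, and adjusted p = 0.59 with an estimated correlation). TRP3 was 4.83-fold and SER1 2.90-fold lower, while SER3 was 3.17-fold higher (adjusted p = 2.77e-10, 8.12e-07 and 1e-06 in the authors' deposited table).

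Lists of phospholipid synthesis, drug export, DNA replication, anaerobic growth and phosphate supply passed upward at the preset correlation. Of 25 phospholipid synthesis genes 10 rose and 0 fell (12 and 0 adjusted over the list alone, median log2 fold change 0.70, camera adjusted p = 6.09e-06, and adjusted p = 0.59 with an estimated correlation). The methyltransferase OPI3 was 4.36-fold and the decarboxylase PSD1 2.77-fold higher (adjusted p = 1.86e-06 and 1.72e-05 in the authors' deposited table). Drug and weak acid export had 7 rises and 1 fall among 21 (9 and 1 adjusted over the list alone, camera adjusted p = 0.000781, and adjusted p = 0.59 with an estimated correlation): TPO1, PDR12 and YOR1 were 3.51-fold, 3.29-fold and 2.96-fold higher (adjusted p = 4.02e-08, 3e-07 and 1.23e-06 in the authors' deposited table). Histone and replication genes had 6 rises and 0 falls among 28 (8 and 0 adjusted over the list alone, camera adjusted p = 0.00198, and adjusted p = 0.59 with an estimated correlation). The histone gene HTA2 was 3.63-fold and RNR1 2.51-fold higher in the authors' deposited table. Anaerobic genes and seripauperins had 8 rises and 1 fall among 32 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0142, and adjusted p = 0.59 with an estimated correlation). CYC7, a cytochrome c isoform, was 4.03-fold higher and ROX1, the repressor of hypoxic genes, 3.43-fold lower (adjusted p = 6.67e-10 and 1.22e-07 in the authors' deposited table), and the seripauperin genes are near-identical copies. Phosphate regulation had 6 rises and 0 falls among 20 (6 rises and 1 fall adjusted over the list alone, camera adjusted p = 0.0204, and adjusted p = 0.62 with an estimated correlation). PHO8, a vacuolar phosphatase, was 2.82-fold higher in the authors' deposited table.

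The remaining lists did not pass. Their counts of rises and falls were 5 and 2 of 20 for trehalose and glycogen metabolism, 1 and 1 of 24 for autophagy, 4 and 1 of 25 for sulfur assimilation, 4 and 1 of 27 for nitrogen catabolite repression, 3 and 4 of 30 for metal regulation, 2 and 3 of 23 for thiamine and vitamin B6 synthesis, 2 and 5 of 27 for ergosterol synthesis, 2 and 1 of 26 for mating genes, 5 and 2 of 41 for meiosis and sporulation and 4 and 3 of 25 for cyclins and the cell cycle (camera adjusted p from 0.148 to 0.98). Adjusted over the list alone, the counts were 6 and 3 for trehalose and glycogen metabolism, 2 and 4 for thiamine and vitamin B6 synthesis, and the same as above for the others. GPH1, glycogen phosphorylase, was nevertheless 4.87-fold higher and RME1, a repressor of meiosis, 5.68-fold lower (adjusted p = 0.00023 and 0.000162 in the authors' deposited table). Of the 8 genes that commonly mark strain construction 2 rose and 4 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.532). TRP1 was 4.30-fold higher (15650 and 67326, adjusted p = 1.67e-11 in the authors' deposited table) and LEU2 2.38-fold higher, whereas LYS2 and ADE2 were 2.75-fold and 3.47-fold lower (adjusted p = 0.000432, 1.39e-05 and 1.4e-05 in the authors' deposited table). Dividing each column by its own total in place of the authors' scaling would raise each log2 fold change by 0.15, which leaves the sign of the median of each of the 20 lists as it is.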

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

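The limma fit, its use for gene lists, the scaling by column totals and the 2-fold threshold by direction were chosen after seeing the data. No paired analysis was possible because the deposited columns are strain means and the recovered libraries carry no replicate number. The authors' calls kept within 1.5 times of 1296 with no low value filter (1311), a mean of at least 10 (1344), a 2-fold threshold (887) and limma on the recovered reads (1742). In the recovered libraries, limma without an intensity trend gave 691 calls (371 higher, 320 lower) against 1742 (843 and 899) with it, and the cause was not tested. Leaving out 1 library, which leaves a lone library assumed to vary like the other strain, gave 429 to 1354 calls, 192 to 673 higher and 231 to 681 lower; fewer samples enter each such fit. It was 1354 without parental library A, 822 without parental library B, 440 without deletion library A and 429 without deletion library B. Of the 20 named rises and falls that limma could test, 11 to 19 passed with 1 library left out (11 without deletion library A, 13 without deletion library B). Lists past the threshold numbered 20 on the authors' p-values, 13 on the recovered libraries, where abundant members are missing, 0 with camera's estimated correlation (0 also at an unadjusted p below 0.05) and 2 with fry. The form with an estimated correlation has few residual degrees of freedom here, so hardly any list could pass it. YGP1 had log2 fold changes from -1.80 to -1.63 under the pseudocounts and rescalings run on its means; filters did not apply to it, and quantile normalisation, limma and leaving out libraries were not run for it because its reads were not recovered. Over the 184 genes that the naming rule takes and 2096 alternative values, 1900 stayed on their side of the threshold, 191 no longer passed, 5 newly passed and 0 changed sign. Of those 191, 70 came without deletion library A, 56 without deletion library B, 24 without parental library B, 8 without parental library A, 30 without the trend and 3 with quantile normalisation. The share of calls that were higher lay between 47.8% and 48.7% across the scalings fitted. The planned count-based tests and their normalisations were not run because the deposited values are not counts per library. Depth limits the features with few reads in one strain, whose ratios have wide intervals.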

Other observations

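The gene sets of the first paragraph and all tests below, except that of sequence shared by YGP1 and SPS100, were chosen after the result was seen. Gene sets built from the annotation's functional terms, and a set of retrotransposon genes, were tested, and of 570 such sets 36 passed the pre-ranked camera test on the authors' p-values. With an estimated correlation on the recovered libraries 0 of 569 sets passed limma's camera (0 also at an unadjusted p below 0.05). As for the fixed lists, that form has few residual degrees of freedom with 2 libraries per strain, so hardly any set could pass it. The retrotransposon Gag and Pol genes had 19 rises and 0 falls among 38 (camera adjusted p = 9.93e-12 over the 570 sets, and adjusted p = 0.998 with an estimated correlation). YER160C had a log2 fold change of 3.11 in the authors' deposited table, but these copies are near-identical, so values of single elements are uncertain. The term for structural constituents of the cell wall had 9 falls and 1 rise among 11 genes (camera adjusted p = 1.59e-06; too few members were recovered for an estimated correlation). All 11 belong to the fixed list of 33 cell wall mannoprotein genes, which did not pass (camera adjusted p = 0.0701) and pointed up on the recovered libraries. There, CWP1, PIR1, CCW12 and SED1, which fell, were among the members missing. The log2 fold changes of CWP1, PIR1, CCW12 and NCW2 were -2.99, -2.59, -2.44 and -1.98, and that of TIR1 was 1.29 in the authors' deposited table. Eisosome genes, which shape furrows of the plasma membrane, had 8 falls and 0 rises among 16 (camera adjusted p = 9.63e-05, and adjusted p = 0.998 with an estimated correlation), including PIL1 at -1.83 and LSP1 at -1.50 in the authors' deposited table. Phosphatidylcholine synthesis had 7 rises and 0 falls among 11 (camera adjusted p = 0.00145, and adjusted p = 0.998 with an estimated correlation). Translocation of proteins targeted to the ER membrane by the signal recognition particle, a part of the secretory pathway whose fixed lists did not pass, had 5 rises and 0 falls among 10 (camera adjusted p = 0.0322, and adjusted p = 0.998 with an estimated correlation from 5 recovered members, where the test pointed down).

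The strain labelled YGP1 deletion kept 29.1% of the parental YGP1 level, and parental RNA or cells mixed into its libraries would bring each parental transcript at that ratio or more, yet 9 features with a parental mean of at least 10000 lay below 14.5% of the parent, 0.5 times that ratio, in both deletion libraries. They were counted among the 134 such features with recovered deletion reads, a selection that leaves out features abundant in the deletion strain. A first bound, more than 20 features with a parental mean of at least 100, had not been met (14 lay below, among 5112 with recovered deletion reads) and was replaced by this one after that count was seen. Reads of SPS100 counted on YGP1 would need long shared sequence, and the longest exact run shared by the coding sequences in R64 was 17 bases. A part of the transcript left by the deletion stays open, because totals per gene hold no positions; a true fall of an intact gene cannot be told apart from it.

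TRP1 was 4.30-fold higher in the deletion strain. Induction of the whole tryptophan pathway would raise TRP2, TRP3, TRP4 and TRP5, whose median log2 fold change was -1.44 and of which TRP2, TRP3 and TRP4 fell in the authors' deposited table. An added TRP1 copy, as used in strain construction, is a candidate explanation that cannot be told apart from other changes at TRP1, because no DNA coverage was used here.

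Cytosolic ribosomal protein genes had a median log2 fold change of -1.17. Gene length would lower other features of the same coding length too, yet 100% of 1000 length-matched sets of other features had a median more than 0.5 above it (their medians ran from -0.28 to 0.31). Differences between cultures of one strain may account for part of the shift: the parental libraries differed by a median log2 of 0.57, 0.503 of the difference between strains of -1.13 and just past the bound of 0.5 set for this explanation. That bound was passed in the parent only, since deletion library B over deletion library A had a median log2 of -0.17. Both deletion libraries lay below both parental libraries for 124 of 137 genes. The labelled genotype and differences between cultures both stay open as explanations. Differences between cultures were examined for these genes only, although parental library A lay closer to both deletion libraries across features too.

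SED1 made up 6.16% of all normalised reads in the parent and 3.38% in the deletion strain. ENA2 had 309 reads in the parent and 1 in the deletion strain, while its neighbours ENA1 and ENA5 had log2 fold changes of -0.87 and 0.15 in the authors' deposited table.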
